A study of Mus musculus with 6 samples.

How the data were processed

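Messenger RNA of pancreas was profiled by sequencing in 6 Ela-myc mice aged 3 months, 3 with wild-type Parp2 and 3 with a Parp2 knockout, each library from a different animal per the series design text. Ela-myc mice carry Myc under the elastase promoter, which is active in the enzyme-secreting acinar cells of the pancreas, and they form pancreatic tumours. Per the labels' protocols, tissue was kept in RNAlater and homogenised, and stranded mRNA libraries were made from total RNA. Those protocols speak of tumour samples, whereas the tissue label is pancreas and the submitters named the deposited data preneoplastic. No sample label records which part of the organ was taken or whether it held tumour.

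The authors deposited gene counts and a table of log2 values, both with Ensembl gene identifiers, symbols and positions. The deposited counts were whole-number read counts per gene that had not been normalised. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.3a and DESeq2 1.28.1 were used with the mouse genome GRCm38 (mm10). The notes attach no role to each tool, and the counting program, its strand setting, the gene annotation release and the treatment of reads with several matches are not given in the sources used here. Genes that overlap, or that have near-identical copies, therefore have uncertain counts. The deposited log2 values matched log2 of the counts divided by DESeq2 size factors plus 1, with differences of at most 5.2e-14, so both tables hold the same measurement and only the counts entered the main test.

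Counts summed to between 28105021 and 32055565 per library over 29721 listed genes. At this depth the Wilson 95% confidence interval of a share of counts is narrow, and it covers counting error only, since these reads carry no molecular identifiers. No pair of libraries of 1 genotype agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts in the pair was between 29.1 and 461.

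Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM scaling and the default group-wise expression filter, which left 17652 genes. The design held genotype alone, and p-values were adjusted by the Benjamini-Hochberg method with 0.05 as the threshold. CPM values are counts scaled to library size and TMM factor in the usual way. Log2 fold changes are knockout minus wild type, and each standard error (SE) was taken as the size of the log2 fold change divided by the square root of its F statistic. For genes with no count in a genotype the fold is a lower bound computed from 3 counts summed over that genotype. For genes with 1 to 3 counts the ratio is given with an exact binomial 95% interval, covering counting error only.

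A set of 31 gene lists for cell types, pathways and tissues that pancreas pieces could hold was fixed before the data were examined, as were the genes to be named and the main alternatives. Lists with at least 3 tested members were compared with all other genes by camera from limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were the alternatives. Fry asks whether the list itself changed and makes no comparison with other genes. List medians per library use log2(CPM + 0.5) relative to the wild-type mean of each gene. A further 9 lists were chosen after the data had been seen and are reported apart.

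The named genes were Parp2, Myc, and in each direction the 12 genes with the largest log2 fold change. Those 12 had to pass the threshold, to have a mean of at least 1 CPM and groups that did not overlap, and not to be predicted genes, clones, pseudogenes or antigen receptor segments. To these came up to 4 members with the smallest p in each list with a called member or a passed test, and the 3 called genes of smallest p within 5 Mb of Parp2. Genes singled out outside this rule are said to have been chosen after their values were seen. Gene overlap and strand came from GENCODE vM21, built on GRCm38.

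Alternatives were DESeq2 size factors, scaling without digestive enzyme genes, other count filters, the DESeq2 1.42.0 Wald test, limma-voom with and without sample weights, limma on the deposited log2 values, other thresholds, sex as a term, and leaving out each library. Library totals as the only scaling, the median log2 CPM of the digestive enzyme genes as a covariate, and counts of list members without knockout replicate 3 or another library were added after the data had been seen. The procedure was tested on simulated counts of 17652 genes with the means, depths and dispersions of this comparison. Only 100 genes changed 2-fold, 100 changed 4-fold and the T cell list were altered, against 53% of genes called in the real comparison. The rates that follow need not hold for the real calls. The edgeR test called 25 of 100 genes changed 2-fold and 86 of 100 changed 4-fold, and 6.56% of its calls were unchanged genes. The DESeq2 Wald test called 60 and 95 of these, with 31.6% of its calls unchanged. Camera called 1 of 31 lists, the list that had been shifted. Each gene was drawn independently, so the simulation cannot tell how often camera errs where list members vary together.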

Results

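Transcript levels were measured by RNA sequencing in the pancreas of 3-month-old Ela-myc mice, a pancreatic tumour model driven by Myc, to ask how loss of PARP2 bears on tumour development. PARP2 is a nuclear enzyme that adds ADP-ribose chains at DNA breaks. There were 3 animals with wild-type Parp2 and 3 knockouts, and library totals were 31016968, 28105021 and 30121583 counts in wild type and 31087607, 30261153 and 32055565 in knockout. Y-linked transcripts and Xist showed males in wild type replicates 1 and 2 and knockout replicate 1, and females in the other 3 libraries.

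Parp2 itself (ENSMUSG00000036023, chromosome 14, 50807841 to 50821301, GRCm38) was lower in every knockout library, with 14.4, 12.4 and 13.6 CPM against 40.5, 36.4 and 37.5 CPM in wild type. The mean was 13.5 ± 1.01 CPM in knockout and 38.1 ± 2.08 CPM in wild type (SD, n = 3 each), a log2 fold change of -1.50 (SE 0.097, edgeR adjusted p = 0.00201). Reads therefore still mapped to Parp2 in the knockout, and the labels do not say which part of the gene was removed. Myc (chromosome 15, 61985391 to 61990374), the driver of the model, was also lower, at 104 ± 65.3 CPM against 304.5 ± 75.5 CPM (SD, n = 3 each; log2 fold change -1.55, SE 0.476, edgeR adjusted p = 0.0366). Its count would include reads of any Myc transgene of mouse sequence. The Myc call ended when any library other than knockout replicate 2 was left out, with adjusted p up to 0.12. It also ended with library totals as the only scaling, no count filter or the acinar level as a covariate (adjusted p = 0.0561, 0.101 and 0.0897).

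Digestive enzyme genes, the main product of acinar cells, took 29.3%, 31.0% and 23.9% of all counts in wild type but 4.55%, 15.2% and 0.0376% in knockout replicates 1, 2 and 3 (Wilson 95% interval of the last, 0.0369% to 0.0383%). The mean share was 28.1% ± 3.72 in wild type and 6.58% ± 7.76 in knockout (SD, n = 3 each; two-sided exact permutation p = 0.10, the smallest that 3 against 3 allows). Knockout replicate 3 was thus almost without acinar transcripts, and knockout replicate 2 was nearest to wild type.

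**Figure D1:**
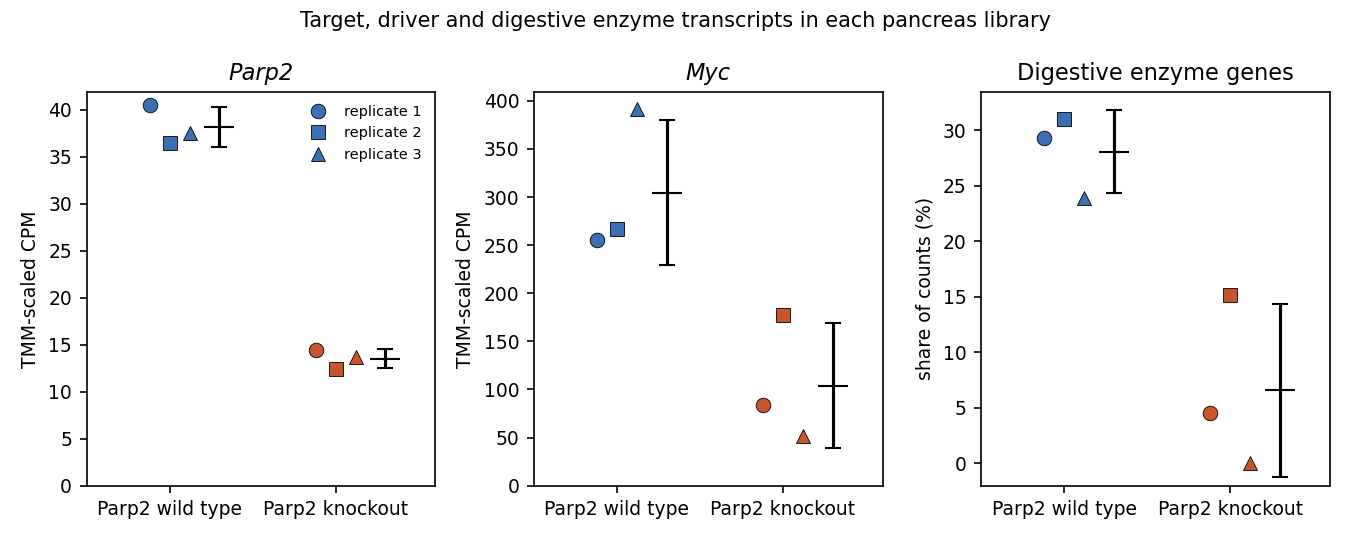
TMM-scaled CPM of Parp2 and Myc and the percent of counts from digestive enzyme genes, by genotype; symbols are libraries, and the bar and whiskers give mean ± SD of 3 libraries. Parp2 was at 12.4 to 14.4 CPM in every knockout library, whereas the enzyme share ran from 0.0376% to 15.2% among them.

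Of 17652 genes tested, 4938 were higher and 4415 lower in knockout (edgeR adjusted p under 0.05), and 2683 and 1895 of these had an absolute log2 fold change of at least 1. The first principal component held 78.7% of the variance and separated the genotypes. It also ordered the libraries by their digestive enzyme share. Wild type replicates 2, 1 and 3 stood at -106.6, -75.6 and -72.7, and knockout replicates 2, 1 and 3 at 27.1, 82.2 and 145.6. Genotype and acinar content cannot be told apart along this component. Scaling decided part of the balance: with library totals only, which moved the median log2 fold change by 0.40, 7475 genes were higher and 2160 lower, so that 77.6% of calls were higher against 52.8%. Without knockout replicate 1, 3602 were higher and 2543 lower.

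The largest rise was in Ccnb1ip1, which encodes a ubiquitin ligase of meiotic crossing-over and lies next to Parp2. It had 3 counts in all wild-type libraries together and 352 in knockout, a ratio of 84.9 (95% interval 28.8 to 414), although it overlaps the RNA gene Rpph1 on the same strand, so that its reads are uncertain. Coch, which encodes cochlin, rose from 0.476 ± 0.506 to 13.1 ± 3.92 CPM (SD, n = 3 each). Pck1, which encodes an enzyme of gluconeogenesis and of glycerol synthesis in fat, rose from 21.6 ± 8.56 to 489.3 ± 244.7 CPM (log2 fold change 4.50, SE 0.529, edgeR adjusted p = 0.00265). Cd209b, a lectin of marginal zone macrophages, and Fcamr, an Fc receptor for IgA and IgM, reached 268.1 ± 26.5 and 16.4 ± 1.89 CPM from 17.2 ± 18.3 and 1.07 ± 1.15 CPM. The endogenous retroviral gene Erv3, the potassium channel gene Kcnj16, the transcription factor gene Dmrt2, the anion exchanger gene Slc4a1, the ribonuclease gene Rnase2a and the pigment enzyme gene Tyr were also among the largest rises, with log2 fold changes between 3.92 and 4.80. Calls of Slc4a1, Rnase2a, Cd209b and Tyr ended when wild type replicate 3 was left out. Those of Slc4a1 without wild type replicate 2, of Cd209b without knockout replicates 1 or 2 and of Tyr without knockout replicate 1 ended too (adjusted p up to 0.0857).

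The largest fall was in Fam83c, with 283 counts in wild type and 0 in knockout, at least 130-fold lower against a floor of 3 counts over the group. Grm2, a glutamate receptor gene, had 154 counts against 2 (ratio 106, 95% interval 29 to 887), and Lin28b, which encodes a fetal RNA-binding protein that blocks let-7, had 191 against 3 (ratio 88, 95% interval 29.7 to 430). Fgf21, which encodes a secreted metabolic factor made by acinar cells and liver, fell from 6.32 ± 3.42 to 0.187 ± 0.149 CPM (log2 fold change -5.09, SE 0.763, edgeR adjusted p = 0.0039). The cadherin gene Cdh16 fell from 7.57 ± 5.59 to 0.132 ± 0.048 CPM and the carbonic anhydrase gene Car14 from 6.90 ± 5.45 to 0.107 ± 0.066 CPM (SD, n = 3 each). Slc10a4 and Mab21l1 fell by 5.58 and 5.11 on the log2 scale. For some of the 12 a single wild-type animal stood far above the others. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, had 26.9 CPM in wild type replicate 3 but 0.509 and 1.20 CPM in the other wild-type libraries. The neuronal genes Nefl and Cplx1 showed 8.92 and 5.89 CPM there and below 1 CPM elsewhere. Serpina7 had 23.9 CPM in wild type replicate 1 and 1.93 and 1.14 CPM in the others. The calls of Th, Nefl, Cplx1 and Serpina7 ended when any knockout library was left out, and that of Th also without wild type replicate 2, with adjusted p up to 0.114.

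Genes of the pancreatic epithelium were lower in all 3 knockout libraries, but to very different depths. The median of 33 digestive enzyme genes lay 2.97, 1.07 and 10.62 log2 units below the wild-type mean in knockout replicates 1, 2 and 3. That of 26 islet hormone and secretory granule genes lay 2.80, 1.47 and 4.86 units below. Because of this spread few members passed the gene test. Among digestive enzymes 0 fell and 1, Amy1, rose by edgeR, and the same held when adjusted over the list alone and at an unadjusted p under 0.05; DESeq2 called 2 lower and limma-voom 3. Amy1 encodes salivary and liver amylase and went from 54.7 ± 3.98 to 124.8 ± 31.8 CPM, although its reads are hard to tell from those of its near-identical pancreatic copies. The pancreatic amylase gene Amy2a5 had 1.01 ± 1.33 against 6.87 ± 0.409 CPM and the chymotrypsin gene Ctrc 8.53 ± 9.71 against 41.6 ± 14.3 CPM (SD, n = 3 each), neither past the threshold. Cpa1, a carboxypeptidase gene chosen after its values were seen, had 28080, 24760 and 18250 CPM in wild type and 3054, 11810 and 11.2 CPM in knockout. Without knockout replicate 3, 5 digestive enzyme genes fell.

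Of 10 acinar transcription factor genes 2 fell, Nr5a2 from 86.7 ± 11.98 to 20.1 ± 16.1 CPM and Gata4 from 89.9 ± 13.1 to 13.5 ± 13.6 CPM. When adjusted over the list alone 0 fell, against 4 at an unadjusted p under 0.05, 4 by DESeq2 and 8 by limma-voom. Ptf1a, the master regulator of acinar fate, had 96.8 ± 4.99 CPM in wild type and 6.55 ± 8.59 CPM in knockout (SD, n = 3 each; edgeR adjusted p = 0.0579). Of 12 injury and regenerating protein genes 2 fell, Fgf21 and Clu, and 1 when adjusted over the list alone. Of 26 islet genes 8 fell and 2 when adjusted over the list alone, among them the prohormone convertase gene Pcsk1 (log2 fold change -3.14, SE 0.547) and the beta-cell transcription factor gene Mafa (-2.91, SE 0.811). Of 25 duct and metaplasia genes 4 fell, Krt19, Agr2 and, named after their values were seen, Sox9 and Krt7, and 2 rose, the tuft cell kinase gene Dclk1 and the carbonic anhydrase gene Car2. When adjusted over the list alone 1 fell and 2 rose. The calls of Nr5a2, Gata4, Krt19, Sox9 and Krt7 ended without any wild-type library or without knockout replicate 1 (adjusted p up to 0.139). Those of Clu and Mafa ended without wild type replicates 1 or 2 or knockout replicate 1, that of Clu also without knockout replicate 3, and that of Agr2 without knockout replicate 1. Without knockout replicate 3 the falls were 6 of 10, 5 of 12, 20 of 26 and 8 of 26 for these lists, without knockout replicate 2 they were 6, 4, 15 and 16, and without knockout replicate 1 they were 0, 1, 2 and 0. Of injury, islet and duct genes DESeq2 called 6, 11 and 9 lower and limma-voom 6, 21 and 15. All 5 epithelial lists were lower by camera, with adjusted p between 5.15e-05 and 0.0204, and lost that call with an estimated correlation, with adjusted p between 0.668 and 0.697. They lost it by fry too, with adjusted p between 0.0695 and 0.259.

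Fat cell genes had the highest median log2 fold change of the 31 lists, 3.05: 15 of 16 rose, and 15 when adjusted over the list alone. Car3 rose from 515.4 ± 204.2 to 5727 ± 953.2 CPM. The lipid droplet genes Plin4 and Cidec rose from 43.1 ± 4.22 to 527 ± 133.8 and from 44.1 ± 19.3 to 587.2 ± 93.7 CPM. Pparg, the master regulator of fat cells, rose from 14.3 ± 3.83 to 62.6 ± 8.25 CPM (SD, n = 3 each; edgeR adjusted p at most 0.00213). Unlike the epithelial genes, they were raised to a like extent in all 3 knockout libraries, with list medians of 3.13, 2.92 and 3.54 log2 units above wild type. The list was higher by camera (adjusted p = 1.20e-13; adjusted p = 0.361 with an estimated correlation). Digestive enzyme shares were 4.55%, 15.2% and 0.0376% in these libraries.

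Lymphocyte genes rose alongside. All 27 T cell genes and all 22 B cell and plasma cell genes rose, the same counts when adjusted over the list alone, with median log2 fold changes of 2.77 and 2.76. The costimulator gene Icos rose from 4.40 ± 1.76 to 34.3 ± 10.7 CPM, the checkpoint gene Ctla4 from 1.97 ± 0.705 to 14.5 ± 5.09 CPM. The follicle-homing receptor gene Cxcr5 rose from 10.9 ± 5.94 to 75.1 ± 14.04 CPM (SD, n = 3 each). Of 20 cytotoxic lymphocyte genes 17 rose, and 17 when adjusted over the list alone, though from a low level. The granzyme gene Gzma went from 1.76 ± 0.257 to 7.78 ± 0.571 CPM and the natural killer receptor gene Ncr1 from 1.48 ± 0.432 to 6.30 ± 0.617 CPM. Of 20 dendritic cell and MHC class II genes 18 rose, and 18 when adjusted over the list alone with 1 falling, among them H2-Aa (log2 fold change 1.27, SE 0.134) and Irf8 (2.11, SE 0.226). Of 8 lymph node stroma genes 6 rose, and 6 when adjusted over the list alone, but 4 without wild type replicate 3 or knockout replicate 1. Madcam1, an adhesion molecule of lymphoid vessels, went from 3.50 ± 1.82 to 29.0 ± 9.86 CPM and the lymphotoxin gene Ltb from 19.1 ± 7.82 to 106 ± 35.8 CPM. Camera called these 5 lists higher, with adjusted p between 2.53e-11 and 0.00106; with an estimated correlation adjusted p lay between 0.361 and 0.489.

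Endothelial genes were also higher, 14 of 16, and 14 when adjusted over the list alone, with a smaller median log2 fold change of 1.08. Kdr, the main VEGF receptor gene, rose from 66.4 ± 3.22 to 172.2 ± 15.4 CPM and Robo4 from 17.2 ± 0.722 to 40.2 ± 1.79 CPM (SD, n = 3 each). The camera adjusted p was 5.34e-09, and adjusted p = 0.361 with an estimated correlation.

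The macrophage, neutrophil and fibroblast lists did not pass as groups in the main camera test. Of 23 macrophage genes 7 rose and 4 fell, the same when adjusted over the list alone, with 7 falling without knockout replicate 2 and 2 without knockout replicate 1. The resident macrophage receptor gene Timd4 rose from 9.23 ± 0.817 to 44.2 ± 5.84 CPM and Csf1r from 238.8 ± 18.99 to 499.6 ± 46.6 CPM. Trem2, Fcgr1, Gpnmb and Cd68, named after their values were seen, fell, but without knockout replicate 1 the calls of Trem2 and Cd68 ended. That of Cd68 also ended without wild type replicates 1 or 2 or knockout replicate 3 (adjusted p up to 0.0883). The list median was -0.03 against a camera direction of higher (adjusted p = 0.52). Of 11 neutrophil genes 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.106, or 0.0339 without knockout replicate 3). With each library left out in turn the camera adjusted p ran from 0.0296 to 0.397. With the acinar level as a covariate 5 neutrophil genes rose and it was 0.00559. Cxcr2 rose from 1.04 ± 0.948 to 8.55 ± 2.75 CPM, a call that ended without wild type replicate 3 (adjusted p = 0.0594). Fibroblast and matrix genes were divided: 5 of 28 rose and 10 fell, or 8 and 10 when adjusted over the list alone (camera adjusted p = 0.384), 4 and 5 without knockout replicate 3, 1 and 3 without knockout replicate 1, and 10 and 4 with library totals as the only scaling. Collagen gene Col1a1 fell from 663.9 ± 139.2 to 286.5 ± 65.7 CPM and the crosslinking enzyme gene Lox from 55.5 ± 6.06 to 27.0 ± 4.82 CPM. Vim, the gene of a mesenchymal filament protein, rose from 367 ± 84.2 to 647.6 ± 59.6 CPM (SD, n = 3 each).

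**Figure D2:**
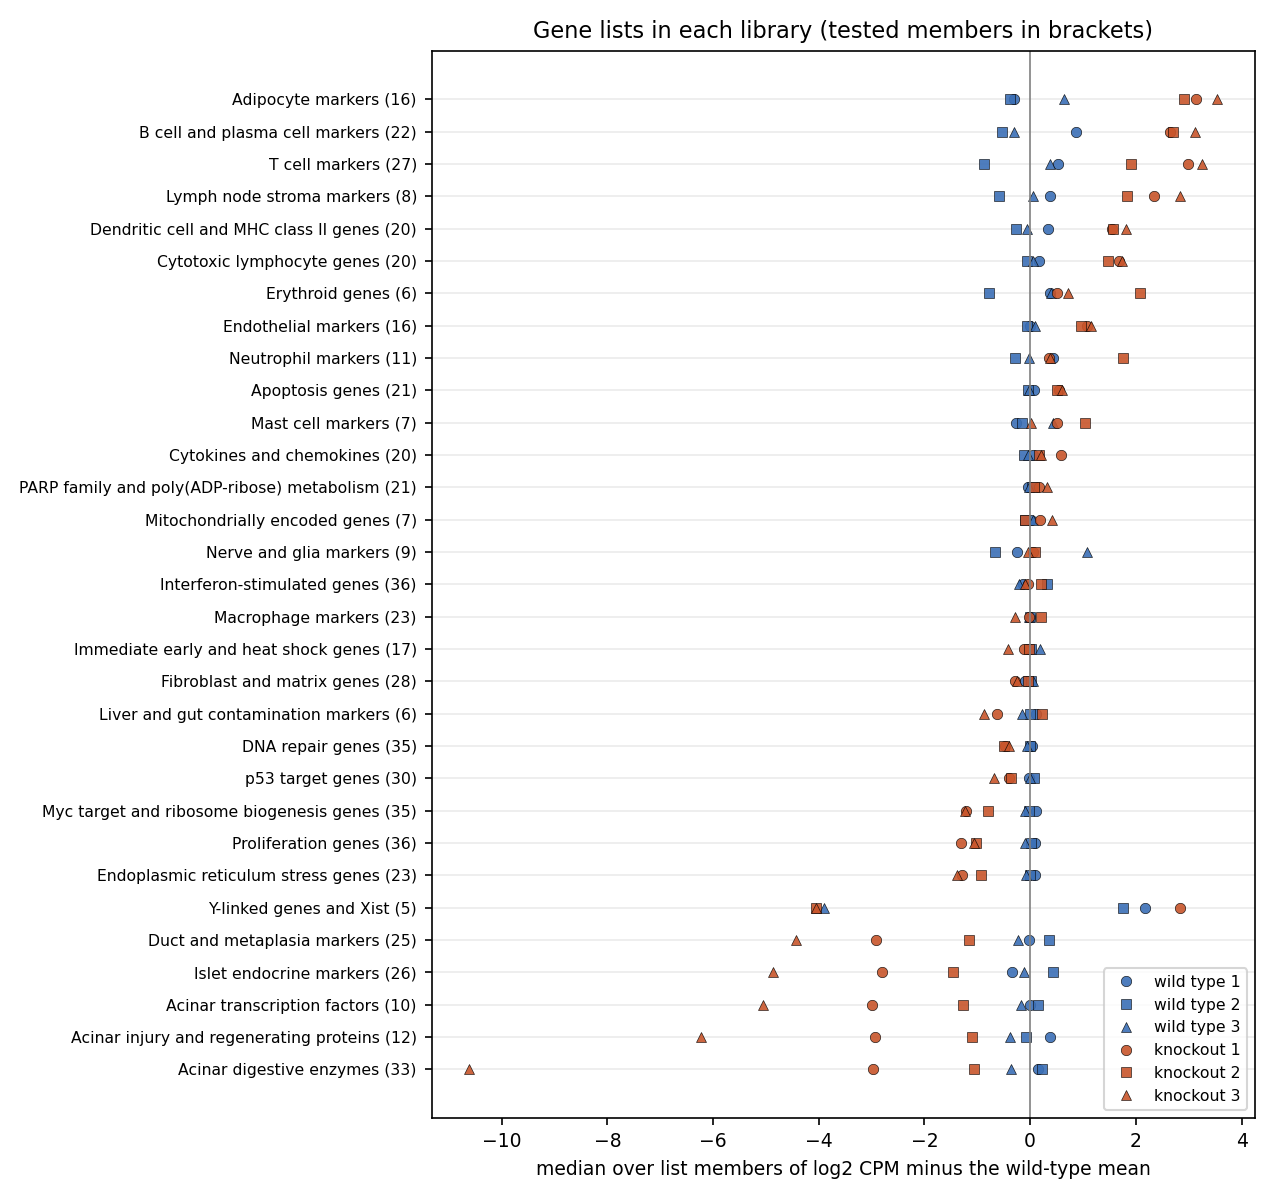
Median over each gene list of log2 CPM minus the wild-type mean, on the horizontal axis in log2 units, for each library, with tested members in brackets; colour gives the genotype and symbols the replicate. In knockout libraries adipocyte medians lay between 2.92 and 3.54, while digestive enzyme medians ran from -1.07 to -10.62; the Y-linked and Xist list separated the sexes.

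Cell cycle genes were lower in knockout to nearly the same extent in its 3 libraries. Of 36 proliferation genes 33 fell, and 33 when adjusted over the list alone, with a median log2 fold change of -1.16 and library medians of -1.30, -1.02 and -1.07. The centromere histone gene Cenpa fell from 62.2 ± 1.10 to 28.6 ± 0.66 CPM. The mitotic kinase gene Plk1 fell from 41.8 ± 4.34 to 11.3 ± 1.72 CPM and the cell cycle transcription factor gene Mybl2 from 22.3 ± 1.68 to 6.10 ± 0.596 CPM (SD, n = 3 each; edgeR adjusted p = 0.00201 for all 3). Of 35 Myc target and ribosome biogenesis genes 33 fell, and 33 when adjusted over the list alone, with a median of -1.10. Tfrc, the transferrin receptor gene, fell from 265.4 ± 37.4 to 82.7 ± 7.55 CPM and Cad, which encodes the enzyme that starts pyrimidine synthesis, from 176 ± 2.04 to 74.1 ± 10.9 CPM. The endoplasmic reticulum stress list, which holds general folding chaperones of secretory cells, was lower for 21 of 23 genes, and 22 when adjusted over the list alone (median -1.28). Manf fell from 228.4 ± 16.9 to 81.1 ± 19.6 CPM and Creld2 from 134.7 ± 14.1 to 44.2 ± 10.9 CPM. With library totals as the only scaling 25 of 36, 27 of 35 and 17 of 23 fell. Camera adjusted p were 3.19e-20, 2.87e-14 and 4.20e-08, with adjusted p = 0.361, 0.369 and 0.369 with an estimated correlation.

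Among 35 DNA repair genes 18 fell and 4 rose, or 19 and 4 when adjusted over the list alone (camera adjusted p = 0.000721; adjusted p = 0.361 with an estimated correlation). The checkpoint kinase gene Chek1 fell from 18.9 ± 0.437 to 6.68 ± 0.994 CPM. The end-joining gene Xrcc6 and the flap nuclease gene Fen1 fell by 1.04 and 1.11 on the log2 scale (SE 0.098 and 0.133). The kinase genes Atm and Prkdc and the end-processing gene Aptx, named after their values were seen, rose, but Aptx lost the call without wild type replicate 2 (adjusted p = 0.0585). With library totals as the only scaling 10 DNA repair genes fell and 9 rose, with a median log2 fold change of -0.01 in place of -0.42. Of 30 p53 target genes 14 fell and 6 rose, or 16 and 6 when adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.564 with an estimated correlation). Gtse1, which is itself expressed in dividing cells, and the apoptosis gene Bbc3 fell by 1.76 and 1.23, whereas Sesn1 and Rrm2b had log2 fold changes of 0.77 and 0.97. With library totals 10 p53 target genes fell and 9 rose, and without knockout replicate 1, 8 fell and 6 rose. Of 21 apoptosis genes 15 rose and 0 fell, or 15 and 1 when adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.361 with an estimated correlation). Birc3 went from 39.5 ± 5.51 to 116.7 ± 17.0 CPM, Xiap from 87.2 ± 5.12 to 152.9 ± 13.8 CPM and Casp1 from 13.8 ± 3.09 to 41.9 ± 0.615 CPM.

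Within the PARP family and ADP-ribose metabolism, a list without Parp2, 9 of 21 genes rose and 2 fell, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.161; fry adjusted p = 0.00258). The 2 that fell, named after their values were seen, were Parp16 and Parp1, with log2 fold changes of -0.91 and -0.30, that of Parp1 turning to 0.11 with library totals as the only scaling. Both calls ended without knockout replicates 1 or 3 or wild type replicate 2, that of Parp1 also without the other wild-type libraries (adjusted p up to 0.127). Without knockout replicate 3, 7 genes rose and 0 fell, without knockout replicate 2, 8 rose and 4 fell, and with library totals 15 rose and 1 fell. Tiparp rose from 18.3 ± 2.18 to 38.4 ± 0.905 CPM, Parp4 from 35.4 ± 2.51 to 81.0 ± 13.5 CPM. Parp8 rose from 18.1 ± 0.57 to 41.1 ± 7.25 CPM and Parp3 from 39.5 ± 4.35 to 78.2 ± 15.9 CPM (SD, n = 3 each).

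Interferon-stimulated genes split: 16 of 36 rose and 5 fell, the same when adjusted over the list alone (camera direction higher, adjusted p = 0.0675, median -0.02). Without knockout replicate 3, 14 rose and 2 fell, with a camera adjusted p of 0.00965, and without knockout replicate 2, 13 rose and 9 fell. DESeq2 called 16 higher and 9 lower. With the acinar level as a covariate 14 rose and 2 fell, and the list passed as higher (camera adjusted p = 0.00428). The proteasome subunit gene Psmb9 and the transcription factor gene Irf1 rose, with Psmb9 at 28.1 ± 1.65 and 85.8 ± 8.19 CPM, Irf1 at 58.1 ± 2.24 and 155.3 ± 21.3 CPM in wild type and knockout (SD, n = 3 each). The chemokine gene Cxcl9 rose from 18.2 ± 2.66 to 54.7 ± 4.44 CPM. The 5 that fell were Bst2, Oas2, Oasl2, Ifi44 and Oas1a, named after their values were seen, with log2 fold changes of -1.12, -1.90, -1.39, -0.96 and -1.34. All except Bst2 lost the call without wild type replicate 2 or knockout replicate 1, and Oasl2, Ifi44 and Oas1a also without knockout replicate 3 or a further wild-type library (adjusted p up to 0.134). Of 20 cytokine and chemokine genes 7 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.316; fry adjusted p = 0.0384). Cxcl12 rose from 141.9 ± 38.8 to 453.7 ± 73.1 CPM, Tgfb1 and Csf1 had log2 fold changes of 1.09 and 0.90, and Ccl7 fell by 1.46. Without knockout replicate 1, 7 rose and 1 fell. Of 17 immediate early and heat shock genes 3 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.561), with library totals 4 rose and 1 fell, and without knockout replicate 1, 1 rose and 2 fell. Jun fell from 113.8 ± 12.1 to 43.6 ± 9.33 CPM and Zfp36 rose from 43.6 ± 1.76 to 89.1 ± 12 CPM.

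The other lists gave few calls. Of 6 erythroid genes 2, Slc4a1 and Alas2, rose, or 1 when adjusted over the list alone, against 6 by DESeq2, 0 by limma-voom and 3 without knockout replicate 1. The haemoglobin gene Hbb-bs had 68.9 ± 27.7 CPM in wild type and 159.4 ± 110.4 CPM in knockout (SD, n = 3 each). Of 7 mast cell genes 1, Kit, fell, and of 9 nerve and glia genes 1, Elavl4, fell, or 1 and 0 when adjusted over the list alone. Of 6 liver and gut genes 3 rose and 1 fell, or 3 and 2 when adjusted over the list alone: Cdh17, Lgals4 and Fabp1 rose and Apoa2 fell. Kit lost its call only without knockout replicate 1 (adjusted p = 0.0534), and Alas2, Elavl4, Fabp1 and Apoa2 lost theirs without that library and others (adjusted p up to 0.12). Without wild type replicate 3, 3 nerve genes rose and 1 fell, and 1 mast cell gene rose and 2 fell. Without knockout replicate 2, 3 liver and gut genes rose and 4 fell. Of 7 mitochondrially encoded genes and of the 5 Y-linked genes and Xist 0 were called by edgeR, also when adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma-voom. Camera directions were lower for mast cell and nerve genes, with medians of 0.82 and 0.07, and higher for liver and gut genes, with a median of -0.30. Camera adjusted p for these 6 lists lay between 0.177 and 0.997. That of the erythroid list ran from 0.00678 to 0.397 with each library left out in turn. It was 0.0421 with the acinar level as a covariate.

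The camera calls of 8 lists higher and 10 lower depended on the preset correlation. Counts of members are no firmer, since members of a list can vary together across the same libraries. They are to be read against the 53% of all genes called. The shares called in the macrophage, fibroblast, cytokine and PARP lists were near that. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.361, against 2 at an unadjusted p under 0.05. Fry passed 15, among them the PARP and cytokine lists, which camera did not pass. Regroupings of the libraries that mixed the genotypes gave 13 to 22 called lists.

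Of 129 tested genes within 5 Mb 71 were called, much as the 53% called among all genes, and the 3 of smallest p fell. They were Psmb5, a proteasome subunit gene (54614119 to 54618022), Rpgrip1 (52110704 to 52163546) and the arginine methyltransferase gene Prmt5 (54507187 to 54517525). Psmb5 fell from 21.7 ± 1.52 to 4.98 ± 0.424 CPM, Rpgrip1 from 24.2 ± 1.95 to 8.09 ± 0.888 CPM and Prmt5 from 76.2 ± 2.52 to 40.7 ± 2.004 CPM (SD, n = 3 each; edgeR adjusted p = 0.00201 for all 3). Rpgrip1 overlaps the gene Supt16 on the other strand, so its reads are certain only if counting used strand. Ccnb1ip1 (50789248 to 50807732) lies on the opposite strand to Parp2 and does not overlap it, although it does overlap Rpph1. The starts of Ccnb1ip1 and Parp2 face each other, with 108 bp between the genes.

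**Figure D3:**
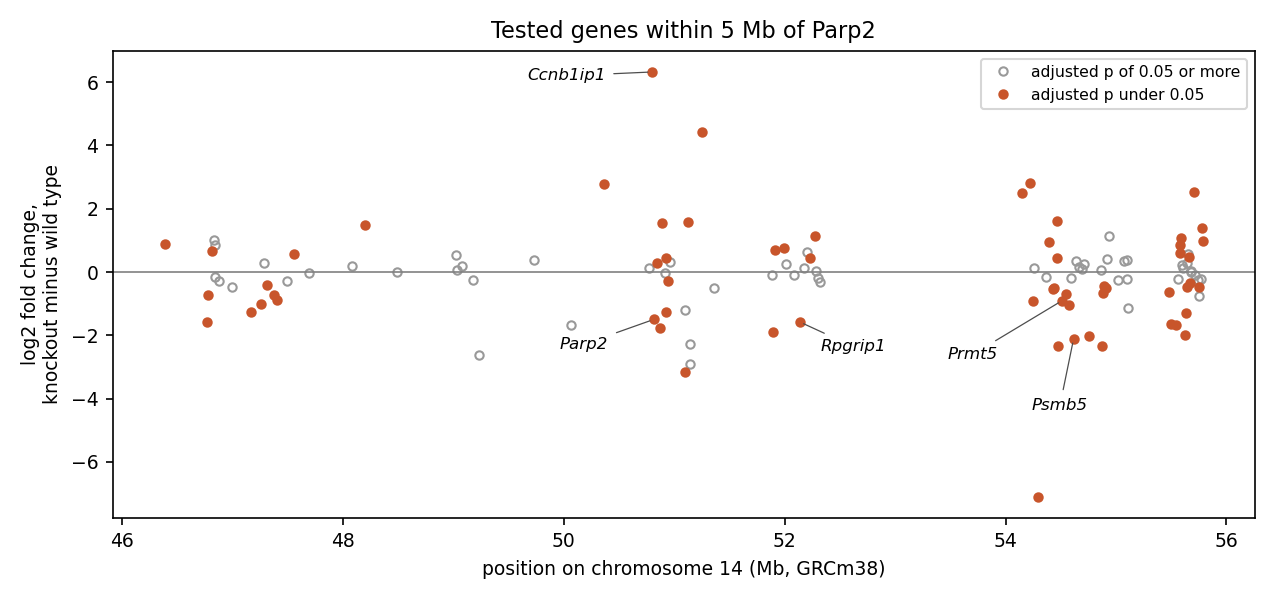
Log2 fold change, knockout minus wild type, of tested genes against their position in Mb on chromosome 14 (GRCm38) within 5 Mb of Parp2, antigen receptor segments left out; filled points passed an adjusted p of 0.05. Ccnb1ip1 stands at 6.32 next to Parp2 at -1.50, and Psmb5 at -2.12.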

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

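Tests with library totals as the only scaling, with the acinar level as a covariate and of list member counts without knockout replicate 3 or another library were chosen only after the result was seen; the others were planned. Parp2 stayed lower and past the threshold under every alternative that was run, with log2 fold changes from -1.54 to -1.09. The Myc log2 fold change stayed below 0 but lost its call with no count filter (-1.53), library totals (-1.22) and the covariate (-0.96), with adjusted p of 0.101, 0.0561 and 0.0897. It ranged from -2.18 to -1.21 with each library left out in turn, with adjusted p from 0.0045 to 0.12. The cause was not decided. In the dilution model described below, Myc differed from the mixture by 0.0276 and 0.0773 log2 units in knockout replicates 1 and 2, so dilution stays open for it. Genes higher and lower numbered 7475 and 2160 with library totals, 3249 and 2609 with the covariate, and 2683 and 1895 with an absolute log2 fold change of at least 1. The sexes were unevenly split between the genotypes, and with sex as a term 4195 genes were higher and 3304 lower. With each library left out they ranged from 3602 to 5125 and from 2543 to 5032. Lists higher and lower numbered 0 and 0 with an estimated correlation, and fry called 5 lower, none of them epithelial, while with each library left out they numbered 8 to 10 and 10. Of 128 named genes called, 103 kept the call with every library left out in turn, 25 lost it at least once and 0 changed sign.

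Lists whose direction turned were ones that had not passed. The mast cell median was 0.80 with DESeq2 size factors, 0.79 with enzymes out of the scaling, 0.87 with no filter, 0.88 by DESeq2, 0.84 by limma-voom, 0.83 with sample weights, 0.89 on the deposited log2 values, 1.32 with the covariate and 0.82 by fry. Liver and gut medians were -0.23 with no filter, -0.65 with sample weights and 0.063 with library totals. Nerve medians were 0.11 with a filter at 1 CPM, 0.066 with sample weights and 0.069 by fry. The mitochondrial median was -0.12 with the covariate, and the Y-linked and Xist median 0.54 with sex as a term. With each library left out medians ran from 0.29 to 1.30 for mast cells, -0.41 to 0.51 for nerve, -2.65 to 0.11 for liver and gut, and 0.065 to 0.30 for mitochondrial genes. No paired analysis was possible because replicate numbers were given in accession order and tie no wild-type animal to a knockout animal. Depth limited genes with few counts: the ratios of Ccnb1ip1, Grm2 and Lin28b have intervals that span more than 10-fold.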

Other observations

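The 9 lists in this paragraph and the next, and every test below except the regrouping of libraries, were chosen only after the result was seen. Genes of the splenic marginal zone and red pulp were higher in knockout, 10 of 12, with 1 lower. Siglec1, a sialic acid receptor of marginal zone macrophages, rose from 85.5 ± 23.8 to 300.1 ± 46.4 CPM. Cd5l, a scavenger protein of tissue macrophages, rose from 11.2 ± 3.50 to 77.4 ± 23.9 CPM (SD, n = 3 each). Spic, which red pulp macrophages need to form, rose from 4.09 ± 2.23 to 17.6 ± 2.47 CPM, whereas Kel fell by 3.48 on the log2 scale. Marco, Stab2, Clec4g and Cd209b lost their calls without wild type replicate 3 or knockout replicate 1, and all of these except Clec4g without knockout replicate 2 (adjusted p up to 0.115). Slc40a1 lost it without wild type replicate 2 (adjusted p = 0.0527). Without wild type replicate 3 or knockout replicate 1, 6 rose. Of 9 Hox genes 6 rose, Hoxa7, Hoxb7, Hoxb8, Hoxb9, Hoxc6 and Hoxc8, or 4 without knockout replicate 1. Hoxa7 went from 1.47 ± 0.272 to 8.81 ± 2.05 CPM and Hoxb7 from 2.26 ± 0.277 to 6.06 ± 1.46 CPM. Of 14 lipogenesis genes 6 rose and Scd2 fell, but 12 rose without wild type replicate 3 and 3 without any other library. Scd1 had 372.8, 652.6 and 3052 CPM in wild type and 7598, 4590 and 19920 CPM in knockout, and its call and those of Dgat2 and Mlxipl ended without any library other than wild type replicate 3 (adjusted p up to 0.131). Camera adjusted p were 0.00119, 0.0021 and 0.0171, with adjusted p = 0.514, 0.514 and 0.579 with an estimated correlation. Fry ended the call of the lipogenesis list (adjusted p = 0.0911).

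Genes of protein synthesis and secretion were lower together. All 20 cytosolic aminoacyl-tRNA synthetase genes fell, 16 with library totals, with Nars going from 348.7 ± 35.8 to 148.3 ± 42.3 CPM and Kars from 227.9 ± 24.3 to 106.5 ± 25.5 CPM. Of 27 secretory pathway genes 24 fell, Sec61a1, the core of the translocation channel, from 639.6 ± 85.3 to 244.8 ± 93.1 CPM, with 19 lower when library totals were the only scaling. Of 25 proteasome genes 21 fell, with a median log2 fold change of -0.43, and with library totals, which moved the median of all genes by 0.40, it was -0.03 and 3 fell. Of 19 sterol synthesis genes 7 fell and 2 rose, or 5 and 5 with library totals (camera adjusted p = 0.0667). Without knockout replicate 3, 7 fell and 0 rose, with a camera adjusted p of 0.0262. Of 12 synaptic genes 7 fell, 3 without knockout replicate 3, and 5 lost their calls without knockout replicate 1 (adjusted p up to 0.114). Wild type replicate 3 stood apart in that list, with a median 1.94 log2 units above the wild-type mean against -0.90 and -0.88 in the other wild-type libraries. Of 9 mesothelium genes 1, Krt19, fell (camera adjusted p = 0.699). The camera adjusted p of the synthetase, secretory, proteasome and synaptic lists were 2.15e-07, 2.68e-08, 3.09e-05 and 0.00505, and with an estimated correlation adjusted p = 0.514, 0.514, 0.514 and 0.579. Fry ended the call of the synaptic list (adjusted p above 0.20).

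Epithelial transcripts were lower in every knockout library. Distorted scaling by abundant enzyme transcripts is argued against, since a scaling factor moves all genes of a library alike. The median of 73 acinar regulator, injury, duct and islet genes minus that of other genes, enzymes left out, was at most -1.26 in the knockout libraries, below the wild-type range of -0.17 to 0.27. Loss of acinar cells alone is argued against too, because the islet median was at most -1.47 in the knockout libraries, below all wild-type libraries. Other tissue such as fat or lymph node in the knockout pieces and a loss of pancreatic tissue in the animals cannot be told apart: 15 of 16 adipocyte genes rose, but no label records what was dissected. A biological effect of Parp2 loss on the gland therefore stays open and untested.

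Lower proliferation and Myc target transcripts may follow from tissue makeup. With the acinar level of each library as a covariate 33 of 36 proliferation genes and 30 of 35 Myc target genes were lower. That argues only against a trend linear in the log2 acinar level as the whole cause. The enzyme medians did not overlap between genotypes, and the covariate did not remove differences in tissue makeup. With it 7 of 26 islet genes stayed lower and 13 of 16 adipocyte genes higher. Tissue makeup as the cause is therefore not excluded. Dilution of wild-type-like tissue by tissue like that of knockout replicate 3 stays open for Myc target genes. Knockout replicates 1 and 2 were modelled as such mixtures, with wild-type-like shares of 16.9% and 54.7%. They lay 0.413 and 0.541 below the mixture in the proliferation median (mean -0.477), whereas wild-type library medians ran from -0.10 to 0.09. The proliferation median of knockout replicate 1, -1.30, was below that of knockout replicate 3, -1.07. For proliferation genes these values argue against such dilution as the whole cause. Dilution by tissue of another profile is not excluded. Differences from the mixture were -0.172 and -0.957 for Parp2 and -0.627 and -1.24 for Psmb5. They were smaller than in the proliferation median for the Myc target median, -0.157 and -0.293, and for Myc itself, 0.0276 and 0.0773. Myc target genes thus lay nearer to dilution than proliferation genes, but the diluting profile was assumed. Slower division in the knockout stays open as well, untested by these bulk values.

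Genes with the clearest changes were more frequent around Parp2, 14 of 120 within 5 Mb (11.7%) in the top 5% of F statistics against 4.95% elsewhere (one-sided Fisher's exact p = 0.00266). A candidate explanation is a chromosome segment around Parp2 that differs between the genotypes, as when a targeted allele keeps flanking sequence of another strain. Of 1389 overlapping windows 29 had as high a share, 22 of them on other chromosomes, and the 14 include Trdc, a T cell receptor gene, and Psme1 and Psme2, which interferon gamma induces. With the acinar level as a covariate 14 of 120 were in the smallest 5% of p (one-sided Fisher's exact p = 0.00266), 12 of them the same genes. That argues only against a trend linear in the log2 acinar level. An origin in tissue makeup is not excluded, since the covariate did not remove differences in makeup. That all 14 stayed called decides nothing, as all 856 top genes elsewhere did too.

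Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, called 9353 genes, and the highest of the other splits called 2. For lists 9 of the 10 splits called at least as many as the real 18, and the highest other called 22. The 10 splits are too few for a share under 0.05.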
